A study of Arabidopsis thaliana with 12 samples.

How the data were processed

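The values used were the deposited log2 signals of 12 Affymetrix ATH1 arrays, computed by the submitters with MAS 5.0. The submitters' design text also names GeneSpring 11.0. Detection calls were not used here. The 2% trimmed mean of the signals, taken on the linear scale, lay between 500.05 and 500.06 on every array, so the arrays had been scaled to a common mean and were not normalised again for the main tests. A value of exactly 0 stood on 139 to 436 probe sets per array. Array medians ran from 6.92 to 7.19, and no pair of arrays held identical columns.

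Of 22810 probe sets 64 were array controls and were left out. Of the other 22746, the probe table used paired 13513 with exactly 1 gene and 503 with several, and 8730 had no gene in it. Gene symbols were updated to those of assembly TAIR10.1 by gene ID for 13436 probe sets and by locus for 48, and 29 were left as they were. A gene is named only where its probe set was paired with that gene alone. All 22746 could be tested whether or not they had a gene, and calls are counted in probe sets unless genes are stated. Of 53 genes with several tested probe sets, 1 was called in opposite directions, in untreated axr2 against untreated wild type.

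A probe set was tested if at least 2 of the 12 arrays exceeded their own 40th percentile of signal, which kept 15025. A linear model with 1 mean per group of genotype and treatment was fitted to all 12 arrays in limma 3.58.1 (R 4.3.3), with moderated variances that followed intensity (eBayes with trend). The model left 6 residual degrees of freedom, the prior added 12, and the median residual SD was 0.219. The groups held 2 arrays each. The 9 contrasts were the response to 24-eBL in each of the 3 genotypes, its mean over the genotypes, the 3 pairwise differences of the response between genotypes, and each mutant against wild type without 24-eBL. Within each contrast p was adjusted over all tested probe sets by the Benjamini-Hochberg method, and a probe set was called at adjusted p under 0.05. Reported SEs are those of the moderated fit. The 2 arrays of a group were taken as independent and their replicate numbers were not used as a block in the main model.

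Gene lists were tested with camera in limma against all other tested single-gene probe sets, with 1 value per gene and with the preset inter-gene correlation of 0.01. Because that preset is small, each list is also given with the correlation estimated from the residuals. A list needed at least 3 tested members, which left 27 lists per contrast, and p was adjusted over those 27. Of 357 members of the lists fixed before the values were seen, 49 had a single-gene probe set in the table used and 40 were tested. The fixed lists whose results are printed were those of XTH, GH3, gibberellin, root hair, and photosynthesis and chlorophyll genes. A further 21 lists were written after the values had been seen, because the fixed lists had so few tested members, and the printed ones among them were SWEET, dehydration, ER body and glucosinolate, nuclear photosynthesis, plastid photosynthesis, plastid gene expression, beta-glucosidase (BGLU), ATG8, chromosome and mitosis, and tetraspanin lists. For pseudogenes only counts are given, and no list test, because a pseudogene silent in wild type and msg2 can pass the filter through high axr2 arrays alone, so that the change itself helps decide which of them are tested.

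Genes to be named were set by rule. The design had set 17 genes that would be named whatever their result; 0 of the 17 had a single-gene probe set in the table used, and they are not analysed here. In each contrast the 5 largest rises and the 5 largest falls were taken among genes whose arrays did not overlap between the compared groups, and up to 4 called genes of each list with the smallest adjusted p. A further 5 rises and 5 falls among genes with a symbol and with signal in the lower group were added after the values had been seen, since many of the largest changes started from a signal near the floor.

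A value at or below the 40th percentile of its array was treated as dim. Where the lower group held dim values, a fold is printed as "at least" and was computed with those values raised to that percentile; no fold is printed where this left less than 1-fold or where the higher group also held dim values.

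The size of the response was compared between genotypes over the genes called risen or fallen in the mean response, a choice that gives no genotype an advantage, and the difference was tested with fry in limma. The same comparison over genes called in wild type alone was run as an alternative and favours wild type by its choice of genes.

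Counts of calls and named genes were recomputed under quantile normalisation, an offset of 16 added to the signal, no filter, a filter at the 60th percentile, no intensity trend, a robust fit, a fit of the compared arrays alone (except for the mean response), a replicate block, an adjusted p under 0.10, a 2-fold minimum, and without each array in turn. The size of the response was recomputed under quantile normalisation, a replicate block, the choice of genes called in wild type, and without each array. The overlaps between genotypes were recomputed under quantile normalisation only, and the list calls with an estimated correlation, with fry and with a replicate block. Subtracting each array's median was fixed in advance for counts and single genes and was added for the size of the response and for list medians after the values had been seen. Raising values to the 40th percentile, for counts and named genes, was also added after the values had been seen.

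In simulated data with the same groups and 15025 tested probe sets, a log2 change of 1 given to 67 probe sets was recovered in 68.7% of them for the response in wild type, in 37.3% for the difference of response between axr2 and wild type and in 89.6% for the mean response. For a change of 0.5 the shares were 10.4%, 4.48% and 55.2%, so small differences of response were mostly missed.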

Results

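Transcripts were measured in dark-grown Arabidopsis thaliana seedlings of the Columbia ecotype on 12 Affymetrix ATH1 arrays. Wild type and the mutants msg2 and axr2 were grown with 100 nM 24-epibrassinolide (24-eBL), a brassinosteroid, or without it (mock). As background, msg2 and axr2 carry dominant point mutations in genes of the Aux/IAA family of auxin-response repressors, so transcript levels of the mutated genes would not check the labels. After 8 h of light the seedlings grew for 4 days in darkness. Each of the 6 groups of genotype and treatment had 2 arrays, described by the submitters as biological replicates. Of 22746 gene probe sets 15025 were tested, and 8150 of these were paired with exactly 1 gene, for 8094 genes. Across the tested probe sets Pearson r was 0.968 to 0.979 between the 2 arrays of a group (median 0.975) and 0.890 to 0.968 between arrays of different groups (median 0.936). The first principal component held 44.4% of the variance and set the axr2 arrays apart from the others, and the second held 14.4% and set 24-eBL apart from mock in each genotype.

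**Figure D1:**
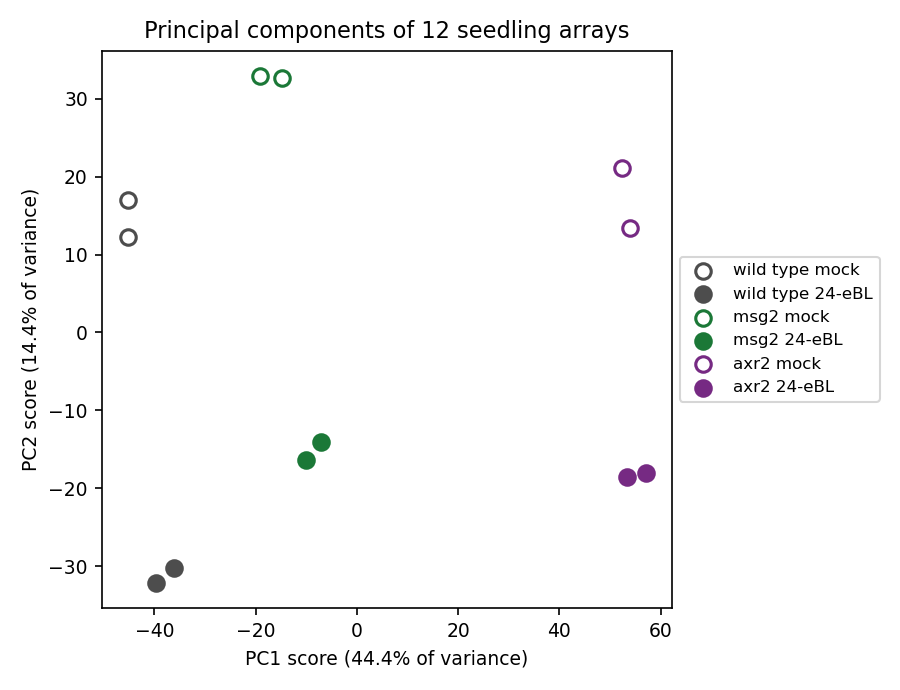
Principal components 1 and 2 of the 12 arrays over the tested probe sets. Open symbols, mock; filled symbols, 24-eBL; grey, wild type; green, msg2; purple, axr2.

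Changes below are log2 changes ± SE from the limma fit with 2 arrays per group, and folds of the same values. A value at or below the 40th percentile of its array was treated as dim, and a fold against a group with dim values is given as "at least", with dim values raised to that percentile. Unless arrays are named beside it, a gene given with a fold kept its call, at adjusted p under 0.05, when any 1 of the 12 arrays was left out. Camera tests of gene lists used a small preset correlation between genes, and p with a correlation estimated from the arrays is given after each. The lists of SWEET, dehydration, ER body and glucosinolate, nuclear and plastid photosynthesis, plastid gene expression, ATG8, chromosome and mitosis, tetraspanin and pseudogenes were written after the values had been seen.

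In wild-type seedlings 24-eBL raised genes of cell-wall xyloglucan remodelling and lowered the root-hair expansin gene EXPA18 and jacalin-related lectin genes. Of 8 tested xyloglucan endotransglucosylase/hydrolase (XTH) genes 4 rose and none fell: XTH20 rose 5.02-fold (2.33 ± 0.23, adjusted p = 2.6e-06), XTH18 2.48-fold (adjusted p = 0.00059), XTH33 2-fold (adjusted p = 0.0032) and XTH19 1.87-fold (adjusted p = 0.00066). The median change of the 8 XTH genes was 0.81 (camera adjusted p = 2.6e-05; adjusted p = 0.062 with an estimated correlation). BCAT4, an aminotransferase of aliphatic glucosinolate synthesis, rose at least 5.13-fold (3.36 ± 0.45, adjusted p = 9.2e-05), with 1 of its 2 mock arrays dim. ECS1 rose 6.57-fold (adjusted p = 1.4e-05), the fatty alcohol caffeoyl transferase gene FACT at least 4.23-fold (adjusted p = 5.8e-05), the glucosyltransferase gene UGT72E1 2.88-fold (adjusted p = 3.7e-06) and TBL41 2.19-fold (adjusted p = 0.0013). AT4G33720 rose 11.2-fold (3.49 ± 0.62, adjusted p = 0.0018), but its adjusted p was 0.057 without WT_BR replicate 1. GH3.3, of the family that conjugates auxin to amino acids, rose 2.51-fold (adjusted p = 0.0035; 0.064 without WT_mock replicate 1), and the fructan exohydrolase gene cwINV6 rose at least 3.05-fold (adjusted p = 0.0025; up to 0.061 without WT_mock replicate 2 or WT_BR replicate 1). Rises of AT1G54020 (at least 1.3-fold), AT1G78990 (at least 1.22-fold) and AT2G43390 (at least 1.32-fold) started from dim values and lost their calls in 9, 3 and 3 of 12 leave-outs, with adjusted p up to 0.27, 0.18 and 0.16.

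Among the genes that fell in wild type, AT5G57785 was 44-fold lower (−5.46 ± 0.24, adjusted p = 1.1e-10), AT2G16005 at least 8.64-fold lower (adjusted p = 8e-07) and AT1G66800 at least 5.27-fold lower (adjusted p = 3.4e-09). The root-hair expansin EXPA18 was 4.05-fold lower (−2.02 ± 0.24, adjusted p = 2.3e-05), and EXPA7, the other tested root-hair gene, was at least 2.41-fold lower but lost its call without WT_mock replicate 2 or WT_BR replicate 2 (adjusted p up to 0.11). The lectin genes JAL33, JAL22 and JAL34 were 3.85-fold, 3.69-fold and 2.01-fold lower (adjusted p = 3.7e-07, 1.3e-06 and 8.1e-05). Of 8 SWEET sugar transporter genes 4 fell, including SWEET11 (1.92-fold lower, adjusted p = 0.00018), with a median of −0.55 (camera adjusted p = 0.0038; adjusted p = 0.15 with an estimated correlation). Of 10 dehydration genes 3 fell, including LEA18 (at least 3.52-fold lower, adjusted p = 0.00024), with a median of −0.90 (camera adjusted p = 0.00064; adjusted p = 0.15 with an estimated correlation). Of 9 ER body and glucosinolate genes 3 fell and 1 rose (median −0.48, camera adjusted p = 3e-04, or 0.27 with an estimated correlation). That list includes the lectin genes JAL33 and JAL22, given above, and BCAT4, which rose. It is therefore not a separate result and does not stand for glucosinolate genes, here or in the mutants. Of 29 nuclear photosynthesis genes CHLM, PSAN and PSBW fell (median −0.25, camera adjusted p = 3e-04, or 0.27 with an estimated correlation).

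In total 701 probe sets were called in wild type, 330 higher and 371 lower (47.1% higher; 4.67% of those tested), of which 339 were single-gene calls counted once per gene. With arrays centred on their medians the split was 247 and 402. Without WT_mock replicate 2 it was 229 and 172. The count depended on single arrays: it was 376 without WT_mock replicate 1, 401 without WT_mock replicate 2 and 351 without WT_BR replicate 1. With a 2-fold minimum it was 386, and without the intensity trend 397.

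In msg2 seedlings XTH20, EXPA18 and the lectin genes JAL22 and JAL33 also responded. XTH20 rose 3.21-fold (1.68 ± 0.23, adjusted p = 0.00019), UGT72E1 2.07-fold (adjusted p = 0.00041), the peroxidase gene Prx37 2.44-fold (adjusted p = 0.00037) and AT1G49570 5.57-fold (2.48 ± 0.19, adjusted p = 4e-07). The 8 XTH genes had a median of 0.62 (3 rose, 0 fell; camera adjusted p = 1.6e-05; adjusted p = 0.056 with an estimated correlation). XTH33 (1.75-fold) and XTH19 (1.53-fold) each lost their call without any 1 of the 4 msg2 arrays, with adjusted p up to 0.19 and 0.24. AT4G33720 rose 7.83-fold, and its adjusted p reached 0.10 without single msg2 arrays. AT5G57785 was at least 37.8-fold lower (−5.34 ± 0.24, adjusted p = 1.6e-10), AT2G16005 at least 8.20-fold lower (adjusted p = 8.6e-06) and AT4G33730 at least 3.26-fold lower (adjusted p = 0.0015). EXPA18 was 7.88-fold lower (−2.98 ± 0.24, adjusted p = 4.5e-07), LCR67 4.13-fold, the carnitine transporter gene OCT1 3.58-fold, JAL22 3.45-fold, LBD16 2.96-fold and JAL33 2.06-fold (adjusted p = 0.00064, 1.7e-05, 5.5e-06, 0.00046 and 0.00076). AT3G15670 (at least 1.94-fold lower) and GH9C1 (at least 1.76-fold lower) lost their calls without msg2_mock replicate 1, msg2_mock replicate 2 or msg2_BR replicate 2, with adjusted p up to 0.24 and 0.33. Dehydration genes fell (4 of 10, median −1.12, camera adjusted p = 5.7e-05, or 0.11 with an estimated correlation). In the ER body and glucosinolate list 4 of 9 genes fell (median −0.37, camera adjusted p = 0.0011, or 0.43 with an estimated correlation). That list includes JAL22 and JAL33, given above, so its median does not stand for glucosinolate genes. Plastid photosynthesis genes had a raised median of 0.29 (adjusted p = 3.5e-04; adjusted p = 0.77 with an estimated correlation), with 1 of 38 called.

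In msg2 589 probe sets were called, 228 higher and 361 lower (38.7% higher); with arrays centred on their medians the split was 273 and 270. The count was 240 without msg2_mock replicate 1, 312 without msg2_mock replicate 2, 236 without msg2_BR replicate 1 and 378 without msg2_BR replicate 2. With a 2-fold minimum it was 360, without the intensity trend 253, and in a fit of the compared arrays alone 936.

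In axr2 seedlings none of the 8 XTH genes was called higher with 24-eBL. XTH20 changed by −0.80 (adjusted p = 0.075) and XTH18 by −0.26 (adjusted p = 0.61), and the median of the 8 XTH genes was −0.12 (camera adjusted p = 0.53), or 0.01 with arrays centred on their medians. XTH19 was called lower at −0.58 (adjusted p = 0.043) but lost its call in 9 of 12 leave-outs, with adjusted p up to 0.21. Other genes did rise: AT3G46270 4.09-fold (2.03 ± 0.24, adjusted p = 4.8e-05), AT3G16530 3.72-fold (adjusted p = 1.4e-05) and the peroxidase gene PRX52 at least 2.44-fold (adjusted p = 0.00092). GH3.3 rose 2.51-fold (adjusted p = 0.0067; up to 0.13 without axr2_mock replicate 1 or axr2_BR replicate 2). AT1G66800 was at least 8.99-fold lower (adjusted p = 1.2e-06), LCR67 at least 3.27-fold (−2.16 ± 0.32, adjusted p = 0.00062), EXPA18 2.93-fold (−1.55 ± 0.24, adjusted p = 0.00092), LBD16 2.49-fold (adjusted p = 0.0039), AT5G04120 at least 2.14-fold (adjusted p = 0.0026) and WES1 (GH3.5) 1.86-fold (adjusted p = 0.0019). Dehydration genes fell (4 of 10; median −0.80, camera adjusted p = 0.0022; adjusted p = 0.30 with an estimated correlation), with LEA18 at least 2.62-fold lower but lost without axr2_mock replicate 1 or axr2_BR replicate 2 (adjusted p up to 0.093). AT3G15670 was at least 1.69-fold lower (adjusted p 0.051 without axr2_mock replicate 1). ER body and glucosinolate genes had a median of −0.30 (2 of 9 fell; adjusted p = 0.0028; adjusted p = 0.42 with an estimated correlation). Photosynthesis genes had raised medians in the plastid (0.57, adjusted p = 5.2e-10; adjusted p = 0.42 with an estimated correlation) and nuclear lists (0.18, adjusted p = 0.0013; adjusted p = 0.42 with an estimated correlation), but only 1 of 38 and 0 of 29 genes were called.

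In axr2 362 probe sets were called, 104 higher and 258 lower (28.7% higher); with arrays centred on their medians the split was 210 and 182, and with quantile normalisation 130 and 245. The share of rises therefore fell from wild type to msg2 to axr2 as deposited but increased in that order with centred arrays, so the 3 splits are not compared. The count was 222 without axr2_mock replicate 1 and 196 without axr2_BR replicate 2. With a 2-fold minimum it was 216, without the intensity trend 165, in a fit of the compared arrays alone 221, and at adjusted p under 0.10 it was 664.

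**Figure D2:**
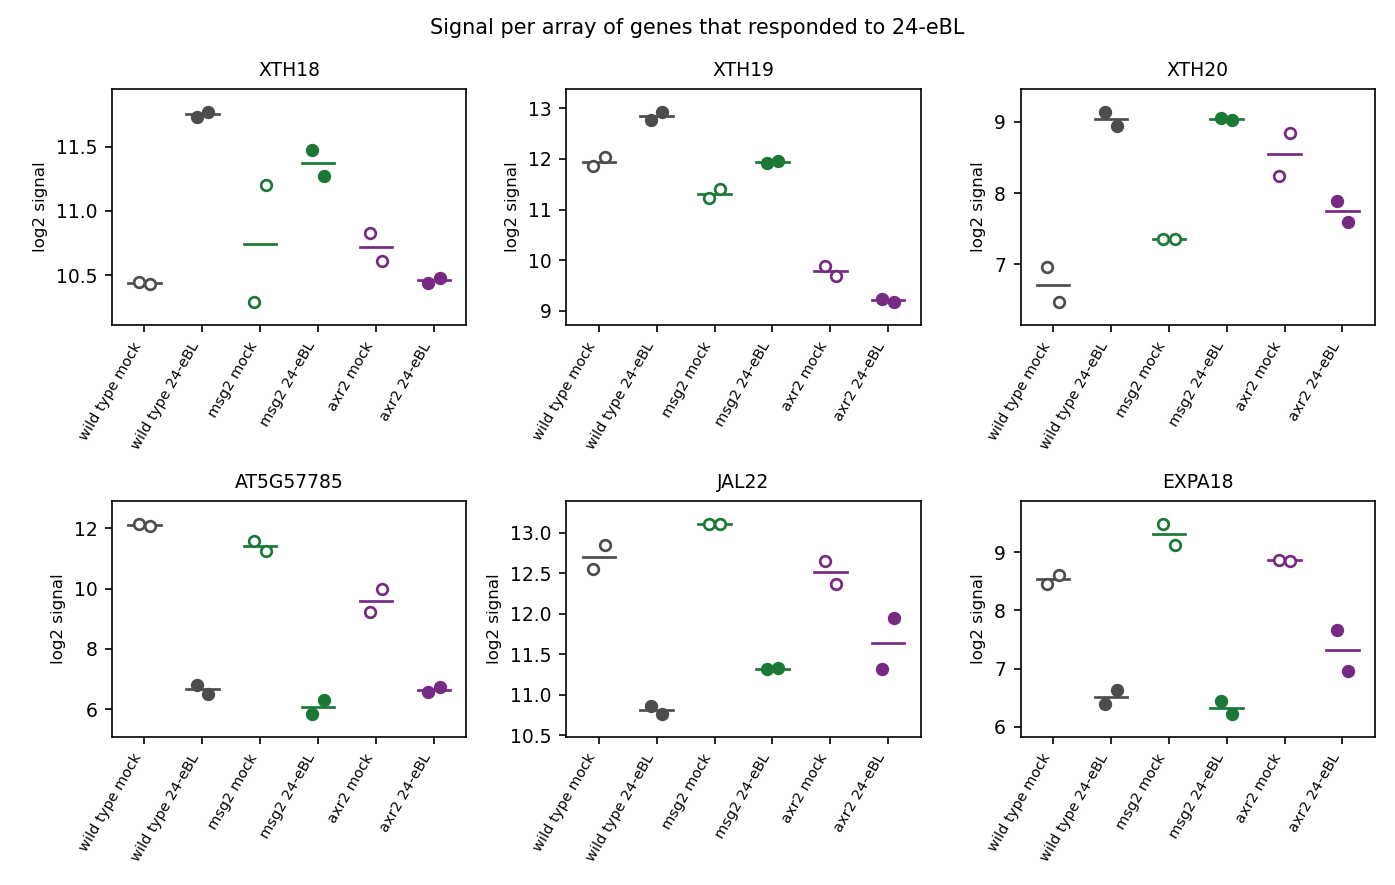
Log2 signal on each array of XTH18, XTH19, XTH20, AT5G57785, JAL22 and EXPA18 in the 6 groups. Bars mark the mean of the 2 arrays of a group.

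Averaged over the 3 genotypes, AT3G46270 rose (1.93 ± 0.14, adjusted p = 2.1e-08), as did FACT (1.38 ± 0.16) and UGT72E1 (1.08). The mean rise of PRX52 (1.93 ± 0.23) was 0.93 with dim values raised, and PRX52 was not called in msg2 (adjusted p = 0.562), nor was FACT in msg2 or axr2. AT5G57785 (−4.58 ± 0.14, adjusted p = 1.5e-13), the root-hair expansin EXPA18 (−2.18 ± 0.14, adjusted p = 3.7e-09), JAL22 (−1.52 ± 0.1) and LBD16 (−1.16 ± 0.14) fell, as did AT1G66800, AT4G33730, LEA18 and EXPA7, whose mean changes with dim values raised were −2.55, −1.37, −1.73 and −1.2. Of the 10 dehydration genes 6 fell and none rose (median −1.03, camera adjusted p = 2.8e-06; adjusted p = 0.058 with an estimated correlation). Of 8 XTH genes 6 rose in the mean (median 0.44, camera adjusted p = 8.7e-05; adjusted p = 0.058 with an estimated correlation), although none was called higher in axr2. The mean response called 1309 probe sets, 561 higher and 748 lower (42.9% higher), or 709 and 580 with arrays centred on their medians, and 301 with a 2-fold minimum. Wild type and msg2 shared 108 raised and 154 lowered probe sets where 5.01 and 8.91 were expected from the sizes of the sets, with 7 called in opposite directions (Pearson r of the changes 0.44, Spearman rho 0.28). Wild type and axr2 shared 27 raised (2.28 expected) and 93 lowered (6.37 expected), with 22 in opposite directions, r = 0.15 and rho = −0.02. The mutants msg2 and axr2 shared 30 raised (1.58 expected) and 104 lowered (6.2 expected), with 9 in opposite directions, r = 0.38 and rho = 0.30. In all 3 genotypes 20 of 517 raised and 72 of 711 lowered probe sets were called.

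Few differences of response between msg2 and wild type were called, and their number moved with the settings. AT2G43620 changed by 3.27 in wild type and 1.08 in msg2 (difference −2.18 ± 0.32, adjusted p = 0.0034). Its treated levels were alike, at 9.48 and 9.07 in wild type and 9.35 and 9.13 in msg2. The difference lay in the untreated levels, at 5.83 and 6.19 in wild type, the first of them dim, and 7.83 and 8.48 in msg2. The difference for AT1G66800 (3.21 ± 0.43, adjusted p = 0.0017) rested on dim values in treated wild type and was 0.33 (adjusted p = 0.87) with dim values raised. The difference for ECS1 was −2.61 ± 0.43 (adjusted p = 0.011; up to 0.058 without WT_mock replicate 1, msg2_mock replicate 1 or msg2_BR replicate 1), and for SIS −1.69 ± 0.26 (adjusted p = 0.0057; 0.051 without WT_mock replicate 1). The 3 tested GH3 genes had a median difference of −0.81 (camera adjusted p = 0.0073; adjusted p = 0.35 with an estimated correlation), and plastid photosynthesis genes one of 0.56 with none called (adjusted p = 0.00018; adjusted p = 0.84 with an estimated correlation). In this difference 32 probe sets were called, 21 higher and 11 lower (65.6% higher), or 26 and 8 with arrays centred on their medians. The split was 20 and 24 with dim values raised to the 40th percentile, 14 and 17 without WT_mock replicate 2 and 22 and 28 without WT_BR replicate 2. The count was 16 without WT_mock replicate 1, 50 without WT_BR replicate 2, 15 without msg2_mock replicate 1 and 16 without msg2_BR replicate 1. It was 14 with no filter, 1 without the intensity trend, 51 in a fit of the compared arrays alone and 57 at adjusted p under 0.10.

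The axr2 response differed from that of wild type in the XTH genes. XTH20 (−3.13 ± 0.32, adjusted p = 3.2e-05), XTH19 (−1.48 ± 0.21, adjusted p = 0.00056) and XTH18 (−1.57 ± 0.3, adjusted p = 0.0065) had negative differences, and the median difference of the 8 XTH genes was −0.74 (camera adjusted p = 6.3e-05; adjusted p = 0.095 with an estimated correlation; −0.55 with arrays centred on their medians). TBL41 rose by 1.13 in wild type and changed by −0.68 in axr2 (difference −1.81 ± 0.28, adjusted p = 0.0012), and BCAT4 changed by 3.36 and 0.03 (difference −3.33 ± 0.63, adjusted p = 0.0069; −2.33 with dim values raised). AT4G33720 rose in wild type and changed by −2.95 in axr2 (difference −6.44 ± 0.88, adjusted p = 0.00048; −4.76 with dim values raised). WES1 changed by 0.25 in wild type and −0.89 in axr2 (difference −1.14 ± 0.21, adjusted p = 0.0053). Some of these genes started from a raised level in untreated axr2. BCAT4 was at 11.04 and 11.32 there, above treated wild type (8.39 and 8.5). XTH20 was at 8.24 and 8.85 against 6.96 and 6.47 in untreated wild type. XTH19 instead started lower, at 9.88 and 9.69 against 11.86 and 12.03. Genes that fell in wild type and had positive differences were AT5G57785 (2.51 ± 0.33, adjusted p = 0.00038), JAL33 (1.47 ± 0.23, adjusted p = 0.0016), OCT1 (1.57 ± 0.28, adjusted p = 0.004) and AT5G62210 (2.76 ± 0.44, adjusted p = 0.0017). Of these, AT5G57785 (9.21 and 9.98 against 12.16 and 12.07) and OCT1 (6.55 and 6.67 against 8.18 and 8.29) started lower in untreated axr2 than in untreated wild type. JAL33 started slightly lower (12.92 and 13.24 against 13.41 and 13.55), and AT5G62210 did not (8.11 and 8.37 against 7.91 and 8.53). Nuclear photosynthesis genes had a median difference of 0.51 with 2 of 29 called (camera adjusted p = 3.7e-07; adjusted p = 0.13 with an estimated correlation). In this difference 391 probe sets were called, 167 higher and 224 lower (42.7% higher), but 320 and 144 with arrays centred on their medians. The count was 189 without WT_mock replicate 1, 195 without WT_BR replicate 1 and 242 without axr2_BR replicate 2. It was 247 with no filter, 126 without the intensity trend and 703 at adjusted p under 0.10.

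Between the mutants, XTH20 (−2.48 ± 0.32, adjusted p = 0.00067), Prx37 (−1.67 ± 0.26, adjusted p = 0.004) and AT5G40590 (−2.8 ± 0.28, adjusted p = 6.9e-05) had negative differences of axr2 and msg2, and AT5G40590 changed in opposite directions, by 1.82 in msg2 and −0.97 in axr2. SIS (2.39 ± 0.26, adjusted p = 0.00015), OCT1 (2.11 ± 0.28, adjusted p = 0.00071) and AT5G57785 (2.39) had differences in the other direction. Each of them was lower in untreated axr2 than in untreated msg2, SIS at 8.18 and 8.45 against 10.72 and 10.84. The 8 XTH genes had a median difference of −0.65 (camera adjusted p = 2.9e-06; adjusted p = 0.041 with an estimated correlation). In this difference 82 probe sets were called, 32 higher and 50 lower. They were 30 and 34 with arrays centred on their medians, 52 and 41 without axr2_mock replicate 1 and 48 and 38 without axr2_mock replicate 2. The count was 42 without msg2_mock replicate 1, 50 without msg2_mock replicate 2, 49 without msg2_BR replicate 1 and 50 without msg2_BR replicate 2; it was 49 with no filter and 17 without the intensity trend.

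The genes raised by 24-eBL responded less in axr2, while for the genes lowered in the mean response no difference between genotypes was called with all arrays. Over the 561 probe sets raised in the mean response the median change was 0.72 in wild type (quartiles 0.46 to 1.23), 0.64 in msg2 (0.42 to 1.03) and 0.35 in axr2 (0.12 to 0.6). The median difference was −0.37 between axr2 and wild type (fry adjusted p = 5e-06; −0.23 without axr2_mock replicate 2), −0.32 between axr2 and msg2 (adjusted p = 1.2e-05; −0.18 without the same array) and −0.11 between msg2 and wild type (adjusted p = 0.0042; lost, with adjusted p up to 0.38, without msg2_mock replicate 1, msg2_mock replicate 2, msg2_BR replicate 2 or axr2_mock replicate 2). The median over all tested probe sets also moved with the scaling of the arrays, for the difference of axr2 and wild type from −0.07 as deposited to 0.12 with arrays centred on their medians. With centred arrays the 3 differences were −0.12 (adjusted p = 0.028), −0.2 (adjusted p = 0.023) and 0.03 (adjusted p = 0.61), and with quantile normalisation −0.27 (adjusted p = 5.8e-05), −0.25 (adjusted p = 6.6e-05) and −0.06 (adjusted p = 0.11). Over the 748 lowered probe sets the medians were −0.66, −0.74 and −0.61 in wild type, msg2 and axr2, and the difference of axr2 and wild type was 0.06 (adjusted p = 0.43; 0.09 with adjusted p = 0.048 without axr2_mock replicate 1, and −0.12 with adjusted p = 0.098 without axr2_mock replicate 2). Over the genes called in wild type, a choice that favours wild type, the differences of axr2 and wild type were −1.06 for raised (adjusted p = 4.4e-07) and 0.8 for lowered genes (adjusted p = 7e-06).

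**Figure D3:**
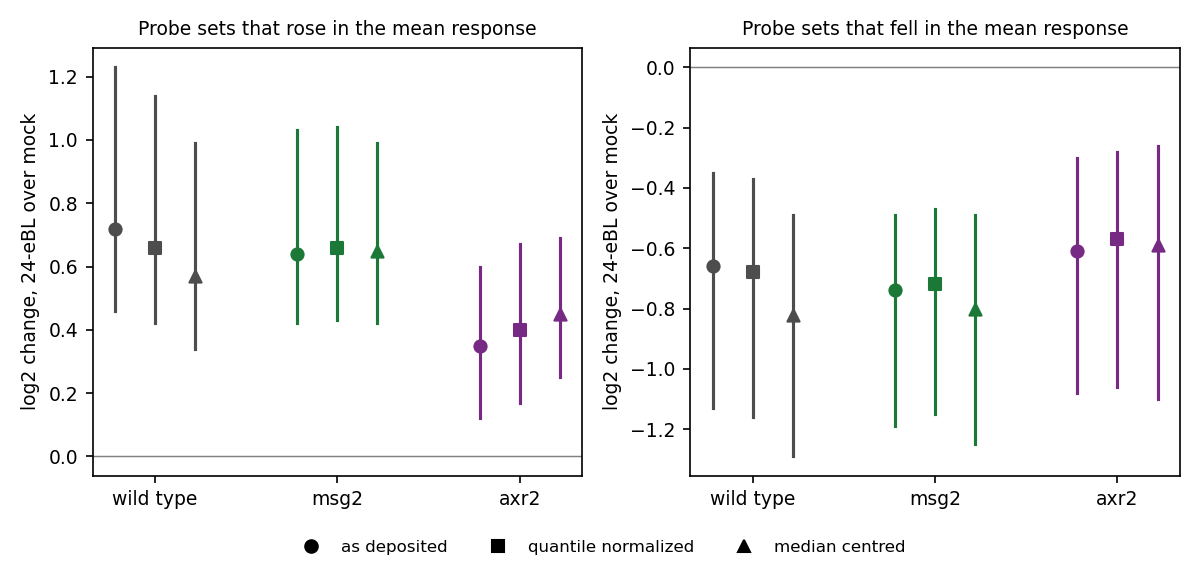
Median and quartiles of the log2 change with 24-eBL in each genotype, for probe sets raised and lowered in the mean response. Circles, values as deposited; squares, quantile normalised; triangles, arrays centred on their medians.

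Without 24-eBL, msg2 seedlings differed from wild type in genes that include IAGLU, AFR, OCT1 and QQS. IAGLU, an indole-3-acetate glucosyltransferase gene, was 2.58-fold lower (−1.37 ± 0.18, adjusted p = 0.00021), and the Aux/IAA gene IAA29 was at least 2.59-fold higher but lost its call without any 1 of the 4 compared arrays (adjusted p up to 0.14). AT2G18010, a SAUR gene, was at least 2.34-fold lower, with adjusted p up to 0.09 without WT_mock replicate 1, WT_mock replicate 2 or msg2_mock replicate 1. AFR, a gene of far-red light response, was 3.96-fold lower (−1.99 ± 0.23, adjusted p = 7.1e-05), PIFI 2.64-fold (adjusted p = 0.0024), UPB1 4.01-fold (adjusted p = 0.0011) and AT3G56290 at least 2.81-fold (adjusted p = 0.00043). QQS was at least 8.44-fold lower in msg2 (−4.53 ± 0.29, adjusted p = 9.5e-08) and higher in axr2 by 2.17 (adjusted p = 1.9e-05). The plastid gene rpl22 was at least 2.97-fold higher (1.96 ± 0.3, adjusted p = 0.00094), OCT1 higher by 1.66 ± 0.2 (adjusted p = 8.5e-05) and CP1 2.2-fold higher (adjusted p = 0.0011). BCAT4 was at least 2.58-fold higher, with adjusted p up to 0.14 without WT_mock replicate 2 or msg2_mock replicate 2. By camera 5 lists were called and none of the 5 with an estimated correlation, among them ATG8 autophagy genes (median −0.34, adjusted p = 0.012; adjusted p = 0.52 with an estimated correlation) and plastid photosynthesis genes (median −0.33, adjusted p = 0.012; adjusted p = 0.61 with an estimated correlation).

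In msg2 against wild type 619 probe sets were called, 319 higher and 300 lower (51.5% higher), but 203 and 371 with arrays centred on their medians. The count was 171 without WT_mock replicate 1, 337 without WT_mock replicate 2, 216 without msg2_mock replicate 1 and 144 without msg2_mock replicate 2. With a 2-fold minimum it was 260, without the intensity trend 181, in a fit of the compared arrays alone 1035, and at adjusted p under 0.10 it was 1043.

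Without 24-eBL, axr2 seedlings differed from wild type in a large part of the transcriptome, with lower EXPA8, gibberellin receptor, sugar transporter and autophagy genes and higher plastid gene expression genes. The pectin methylesterase gene ATPMEPCRD was 52.1-fold lower (−5.7 ± 0.15, adjusted p = 2.4e-14), the expansin EXPA8 11.2-fold (−3.49 ± 0.16, adjusted p = 3.1e-11), ATL8 6.05-fold and SIS 5.12-fold. The XTH genes split: XTH20 and XTH32 were 3.55-fold and 3.69-fold higher, and XTH19 and XTH33 4.48-fold and 3.74-fold lower (median of the 8 genes 0.18, camera adjusted p = 0.87). Among auxin-related genes the kinase gene WAG2 was 3.74-fold lower, IAGLU 2.29-fold, HAT2 2.07-fold and AT2G18010, the SAUR gene, at least 2.06-fold. These are single genes and do not stand for auxin genes as a whole. The 3 tested Aux/IAA genes had a median of −0.05 and the 3 GH3 genes one of −0.53, and neither list was called by camera. GH3.17 was at 10.48 and 10.44 against 10.08 and 10.23 in untreated wild type. The gibberellin receptor genes GID1C and GID1B were 2.75-fold and 1.85-fold lower (gibberellin list of 3 genes, median −0.89, camera adjusted p = 0.034; adjusted p = 0.25 with an estimated correlation). SWEET sugar transporters were lower in 5 of 8 genes and higher in 1 (median −1.28, adjusted p = 0.015; adjusted p = 0.25 with an estimated correlation), with SWEET3 at least 6.36-fold and SWEET11 2.81-fold lower. ATG8 autophagy genes were lower in 7 of 9 (median −0.61, adjusted p = 0.001; adjusted p = 0.35 with an estimated correlation), with ATG8E 3.21-fold, ATG8C 1.68-fold and ATG8F 1.62-fold lower. Dehydration genes were lower in 5 of 10 and higher in 1 (median −0.56, adjusted p = 0.0098; adjusted p = 0.25 with an estimated correlation), with LTI30 4.12-fold, COR47 3.18-fold and HIS1-3 at least 2.44-fold lower, and tetraspanin genes were lower in 4 of 8 and higher in 1 (median −0.54, adjusted p = 0.036; adjusted p = 0.26 with an estimated correlation).

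Higher in axr2 were BCAT4, at least 34.2-fold (6.09 ± 0.45, adjusted p = 1.6e-08, with 1 of 2 wild-type arrays dim), and Prx37, 6.04-fold (2.59 ± 0.19, adjusted p = 1.1e-08). Of 16 plastid gene expression genes 9 were higher and none lower (median 1.21, camera adjusted p = 0.001; adjusted p = 0.35 with an estimated correlation), with rpl22 at least 9.19-fold, rps3 5.46-fold and rps19 3.82-fold higher. Of 12 chromosome and mitosis genes 7 were higher, but 4 with arrays centred on their medians (median 0.52, camera adjusted p = 0.035; adjusted p = 0.57 with an estimated correlation), and the histone genes HTB2 and HTB1 were 2.36-fold and 2.17-fold higher. AT1G58025, dim on every wild-type and msg2 array, was at least 53.8-fold higher (adjusted p = 6.6e-08). Of 62 tested pseudogenes 23 were higher and 5 lower, but pseudogenes silent elsewhere could pass the filter through the axr2 arrays alone, so these counts do not stand for pseudogenes at large. Over 963 pseudogene probe sets chosen as dim on the 4 msg2 arrays the median change was 0.30 (interval 0.20 to 0.43), against 0.33 (0.29 to 0.38) for 4551 coding ones. These intervals drew probe sets as if independent and hold no spread between arrays. Of the 963 and the 4551, 13 and 3 rose from the dim range to above the 60th percentile. Of those 13, 11 were on probe sets that read sequences shared between genes, where it was 11 of 185 against 0 of 55 coding ones (Fisher p = 0.073). On probe sets specific to 1 sequence it was 2 of 778 against 3 of 4496 (Fisher p = 0.16). Of the 23, 10 were on probe sets specific to 1 sequence. Of those on shared sequences, which do not count as separate loci, AT2G13870 was at least 13.5-fold, AT2G12300 at least 21.7-fold, AT2G10640 at least 20.4-fold, AT2G12240 at least 22.4-fold and AT3G30396 at least 17.1-fold higher. With quantile normalisation 18 of the pseudogenes were called higher and with centred arrays 19.

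In axr2 against wild type 5329 probe sets were called (35.5% of those tested), 3078 higher and 2251 lower (57.8% higher). With arrays centred on their medians 1766 were higher and 3389 lower, and with quantile normalisation 2632 and 2528, so which direction held more genes rested on the scaling. With a 2-fold minimum 2236 were called. The changes of untreated msg2 and axr2 shared 283 raised (65.3 expected) and 255 lowered probe sets (44.9 expected), with 8 in opposite directions. The expected numbers take both contrasts as independent, but both use the same untreated wild-type arrays. How much of the excess comes from those arrays was not tested. Pearson r was 0.63 and Spearman rho 0.67, of which part comes from the shared wild-type arrays. Simulated data without any change in either mutant gave r = 0.50 with a covariance of 0.048, against a measured covariance of 0.26. Because that simulation held no changes of 1 mutant alone, the covariances can be compared but the values of r cannot.

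**Figure D4:**
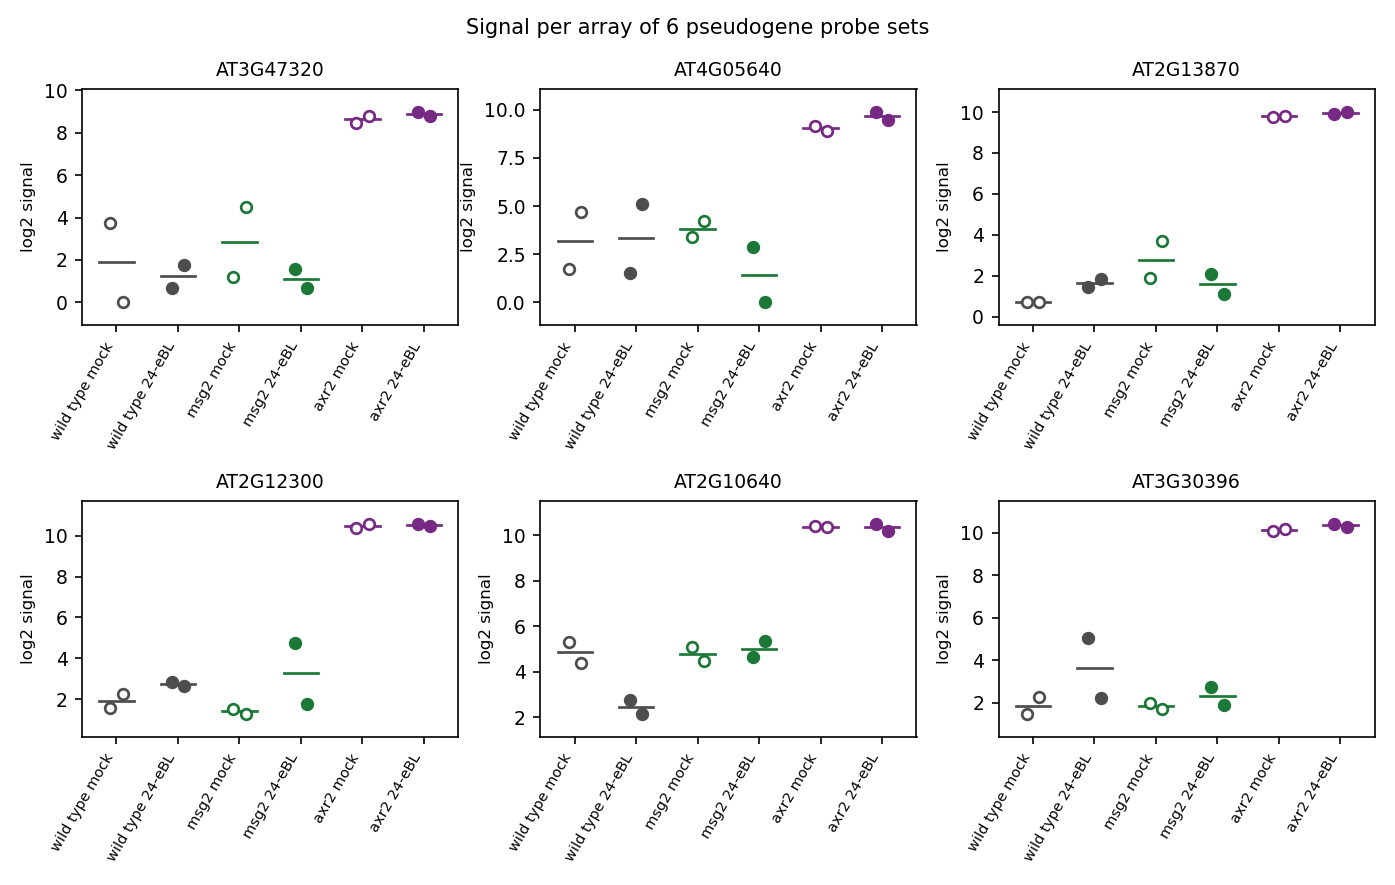
Log2 signal on each of the 12 arrays of the pseudogenes AT3G47320, AT4G05640, AT2G13870, AT2G12300, AT2G10640 and AT3G30396.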

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

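Several of the tests of explanations below were chosen only after the result they concern had been seen. For the pseudogenes they were those of low signal, of scaling and of chromosome position. For the response in axr2 they were those of array noise and of scaling as the source of its size. The tests of the plastid genes and the raising of dim values were also chosen then. Counting the calls in the difference between axr2 and wild type under quantile normalisation had been set before.

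The tested differences of the response to 24-eBL between genotypes are listed here because each passed a test of the difference itself. They comprised 32 probe sets between msg2 and wild type, 391 between axr2 and wild type and 82 between axr2 and msg2. For msg2 minus wild type the named genes with positive differences were AT5G10040 (3.65), AT1G66800 (3.21), AT5G62210 (2.49), AT2G43535 (1.55) and AT1G62510 (1.44), and those with negative ones AT5G55660 (−5.26), ECS1 (−2.61), rpl22 (−2.55), AT2G43620 (−2.18) and SIS (−1.69). For axr2 minus wild type the positive differences were those of SWEET3 (4.06), AT2G16190 (3.9), AT5G62210 (2.76), AT2G16005 (2.63), AT5G57785 (2.51), AT2G10640 (2.38), JAL33 (1.47), PSAN (1.06), LHCB4.2 (1.01), JAL22 (1.01) and SWEET11 (0.93). The negative ones were those of AT4G33720 (−6.44), AT5G04120 (−5.76), WSD1 (−4.56), AT5G55660 (−3.96), AT5G66540 (−3.81), BCAT4 (−3.33), XTH20 (−3.13), rpl22 (−2.33), TBL41 (−1.81), XTH18 (−1.57), XTH19 (−1.48), WES1 (−1.14), TUB1 (−1.09), TPLATE (−1.06) and UGT72E1 (−0.86). For axr2 minus msg2 they were AT5G57785 (2.39), SIS (2.39), AT2G16005 (2.17), OCT1 (2.11), AT5G02160 (2.01), GH3.3 (1.64), AT4G33720 (−5.92), AT5G04120 (−5.82), AT5G52670 (−3.83), AT5G40590 (−2.8), XTH20 (−2.48) and XTH19 (−1.19). Several of these values rest on arrays at background and are not sizes of a change. Others, such as those of AT5G57785, include a different level in the untreated mutant. With dim values raised to the 40th percentile the msg2 minus wild type differences were 2.01 for AT5G10040, 0.33 for AT1G66800 and −0.27 for AT5G55660, none of the 3 called. The axr2 minus wild type differences were then 2.42 for SWEET3 and 2.04 for AT2G16190, which were dim on all 4 axr2 arrays so that their axr2 response was not measured, 2.1 for AT2G16005, −2.4 for AT5G04120 and −4.76 for AT4G33720, and, no longer called, −0.1 for WSD1, −0.77 for AT5G55660, −0.58 for AT5G66540 and −0.09 for AT2G10640. The axr2 minus msg2 differences were then −2.46 for AT5G04120, −4.25 for AT4G33720 and, no longer called, 2.02 for AT2G16005 and −0.75 for AT5G52670. Among gene lists the median differences for msg2 minus wild type were −0.81 (GH3), 0.56 (plastid photosynthesis), 0.17 (nuclear photosynthesis) and −0.44 (BGLU), and none of the 4 was called with an estimated correlation. For axr2 minus wild type they were −0.74 (XTH), 0.61 (photosynthesis and chlorophyll), 0.69 (plastid photosynthesis), 0.51 (nuclear photosynthesis) and 0.35 (SWEET), again with none called with an estimated correlation. For axr2 minus msg2 they were −0.65 (XTH, the only list also called with an estimated correlation), 0.42 (photosynthesis and chlorophyll) and 0.2 (nuclear photosynthesis). The raised genes differed by −0.11 (msg2 minus wild type), −0.37 (axr2 minus wild type) and −0.32 (axr2 minus msg2).

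The smaller response of raised genes in axr2 was weighed against scaling, noise and a raised starting level. Of the 391 probe sets called in the difference, 320 were also called with quantile normalisation (337 in all) and 311 with centred arrays (464 in all), so scaling is not the source of most calls. Centring turned the split from 167 higher and 224 lower to 320 and 144 and left a median difference of −0.12. It also moved the median over all tested probe sets upward, so the change to −0.12 includes a shift common to all of them. How much of the size as deposited may come from scaling stayed undecided. Replicate arrays of axr2 spread 1.08 times as much as those of wild type, taken over mock and treated groups together. The median SD between replicates was 0.178 in axr2_mock and 0.145 in WT_mock, and 0.155 in axr2_BR and 0.164 in WT_BR. Spread between replicates need not shrink a median over many probe sets, so the ratio cannot decide whether noise had a part. Untreated axr2 held the raised genes 0.14 above wild type relative to all probe sets (interval 0 to 0.28), which leaves open whether a raised starting level could be a cause. Of these 561 probe sets 217 were called higher and 114 lower in untreated axr2. The interval, like that of the lowered genes below, drew probe sets as if independent and holds no spread between arrays. The starting level and the difference of response use the same untreated arrays with opposite signs, so an error on those arrays would move both together. For the lowered genes the same relative value was −0.44 (interval −0.54 to −0.32; −0.31 before subtracting the median of all probe sets), which met the bound set beforehand, but it was left open, a ruling made after it had been seen, because a smaller response of these genes was itself not settled: the difference was 0.06 (adjusted p = 0.43), 0.09 without axr2_mock replicate 1 (adjusted p = 0.048), −0.12 without axr2_mock replicate 2 (adjusted p = 0.098), −0.03 and −0.02 without axr2_BR replicate 1 or 2, 0.23 with centred arrays (adjusted p = 0.059) and 0.8 over genes called in wild type (adjusted p = 7e-06), a choice that favours wild type.

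The pseudogenes higher in untreated axr2 were weighed against genomic DNA, low signal, scaling and position, with loss of silencing as the biological alternative; only 10 of the 23 were on probe sets named as specific to 1 sequence, so some may read the same repeated transcript. Over probe sets dim on the 4 msg2 arrays the median difference was 0.33 for 4551 coding ones (interval 0.29 to 0.38) and 0.30 for 963 pseudogenes (0.20 to 0.43). It was 0.13 over all tested probe sets, which are mostly brighter. The 40th percentile of the arrays was itself higher in untreated axr2 (6.34 and 6.31) than in untreated wild type (6.08 and 5.99). A rise of either class can therefore not be told apart from a shift at the low end of the arrays. Both medians were too small for DNA that holds every locus alike to give rises of many-fold. The value of 0.52 over the 185 pseudogene probe sets that read shared sequences (0.26 to 0.78) left DNA weighted by copy number open. The intervals of these medians drew probe sets as if independent and hold no spread between arrays. On both axr2 arrays with 24-eBL, which are not in the contrast though they took part in the filter and the variance, 19 of the 23 lay above every wild-type and msg2 array, and 22 of the 23 passed the filter without them, which argues against noise as the source of all; 18 of the 23 stayed called under quantile normalisation and 19 with centred arrays, and at most 10 lay on 1 chromosome (chromosome 2 of TAIR10.1, 10 of 14 tested there), so scaling or a single region from another source cannot account for all of them but could for a part. Coding genes in pseudogene-rich neighbourhoods rose from the dim range with an odds ratio of 17.9 (Fisher p = 0.028, interval 0.93 to 1050; 2 of 455 against 1 of 4062), which met the criterion set beforehand for loss of silencing but rested on 3 genes, and it was left open because the interval was also required to exclude 1, a condition added after the value had been seen. Each mutant is a single line, so a difference of the line apart from its mutation could not be separated here.

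The plastid gene expression genes higher in untreated axr2 were weighed against more plastid RNA or DNA as a whole. The 16 genes exceeded the 38 plastid photosynthesis genes by 0.85 in the median (interval 0.25 to 1.67, with genes drawn as if independent). The 9 expression genes outside the cluster from rpoA to rpl23 had a median of 0.51, close to 0.36 for the photosynthesis genes. The excess therefore rested on the 7 genes of that cluster, and a similar rise of the other plastid transcripts was not excluded. The 7 genes between rpoA and rpl23 exceeded the other 9 by 1.75 (exact permutation p = 0.0031). That gene cluster was picked after its values had been seen, so the p is no independent test of a rise centred on it. No biological cause of such a rise was tested.

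When the arrays were divided within genotypes in other ways, no other division gave as many called probe sets in the mean response as the real one. Of 100 divisions taken from 108, the real one included, 1 reached 1309. The other divisions had a median of 0. The highest of them gave 631, and it had only 2 arrays of the other treatment on each side, so it kept part of the real contrast.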

How the results depend on the processing

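Raising values to the 40th percentile, and centring arrays on their medians for the size of the response and the list medians, were chosen after the values had been seen. Of 9059 recomputed values of 383 named results, 7835 kept their direction and their side of the threshold and 7 changed sign, all 7 when values were raised to the 40th percentile: AT3G52170 to 0.07 and AT2G10640 to 0.07 (wild type response), AT2G12240 to −0.07 and AT5G06730 to −0.07 (msg2 response), AT4G16745 to −0.04 (axr2 response), AT5G52670 to 0 (msg2 against wild type) and AT2G10640 to −0.09 (axr2 minus wild type). All 7 rested on dim values. In every leave-out 195 of the 383 kept their call. For other moves below the cause was not tested. No detection calls were used here, so changes that start from dim values are limited by the background of the arrays.

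Counts of called probe sets that moved by more than 1.5 times are given with the main count in parentheses. With no filter the differences msg2 minus wild type, axr2 minus wild type and axr2 minus msg2 had 14 (32), 247 (391) and 49 (82). Without the intensity trend the responses in wild type, msg2 and axr2 had 397 (701), 253 (589) and 165 (362), msg2 against wild type 181 (619), and the 3 differences 1, 126 and 17. In a fit of the compared arrays alone the responses in msg2 and axr2 had 936 and 221, msg2 against wild type 1035, and msg2 minus wild type 51. At adjusted p under 0.10 the axr2 response had 664, msg2 against wild type 1043, msg2 minus wild type 57 and axr2 minus wild type 703. With a 2-fold minimum the responses in wild type, msg2 and axr2 had 386, 360 and 216, msg2 against wild type 260, axr2 against wild type 2236 (5329) and the mean response 301 (1309).

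Without 1 array the counts ran from 351 to 838 (wild type response), 236 to 675 (msg2), 196 to 400 (axr2), 144 to 756 (msg2 against wild type), 3589 to 5392 (axr2 against wild type), 15 to 50 (msg2 minus wild type), 189 to 516 (axr2 minus wild type), 42 to 93 (axr2 minus msg2) and 943 to 1384 (mean). The array left alone in its group was assumed to vary like the other groups.

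With a correlation estimated from the arrays camera called 0 lists in each of the 3 responses, their mean, msg2 against wild type, axr2 against wild type, msg2 minus wild type and axr2 minus wild type, and 1 in axr2 minus msg2. Fry called 1 list in the axr2 response (5 with camera), 0 in msg2 against wild type (5) and 1 in msg2 minus wild type (4).

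For the size of the response, median centring turned the difference msg2 minus wild type to 0.03 (raised genes) and 0.06 (lowered genes), and quantile normalisation left −0.06 (adjusted p = 0.11, raised genes). Over genes called in wild type, a choice that favours wild type, the lowered genes differed by 0.45 (msg2 minus wild type), 0.8 (axr2 minus wild type) and 0.31 (axr2 minus msg2), and the raised genes by −0.51, −1.06 and −0.49. Without 1 array the raised genes ran from −0.19 to −0.02, −0.53 to −0.23 and −0.47 to −0.18 for these 3 differences, and the lowered genes from −0.16 to 0.1, −0.12 to 0.21 and −0.02 to 0.2.

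The replicate numbers did not pair the arrays (correlation of deviations −0.08 to 0.071 over 15 pairs of groups). With a replicate block the counts were 677, 556 and 335 (responses in wild type, msg2 and axr2), 559 and 5201 (msg2 and axr2 against wild type), 31, 363 and 77 (differences) and 1248 (mean), and the numbers of called lists did not move.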

Other observations

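The comparison of pseudogene and coding probe sets in the dim range was chosen after the pseudogenes had been seen to differ.

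Other values that stood apart were these. QQS had mean log2 signals of 9.22 in wild type, 4.68 in msg2 and 11.38 in axr2 without 24-eBL. AT1G58025, a coding gene, had log2 signals of 0.46 to 4.02 on the 8 wild-type and msg2 arrays and 11.49 to 12.24 on the 4 axr2 arrays. Of 963 pseudogene probe sets in the dim range 13 rose in axr2, against 3 of 4551 coding ones (odds ratio 20.7, interval 5.68 to 114). Of these 13, 11 were on probe sets that read sequences shared between genes and so are not independent. Among such shared probe sets it was 11 of 185 against 0 of 55 coding ones (Fisher p = 0.073). Among probe sets named as specific to 1 sequence it was 2 of 778 against 3 of 4496 (Fisher p = 0.16). Neither kind of probe set passed 0.05 alone, and the odds ratio of 20.7 pools them. On all 4 axr2 arrays 19 of the 23 pseudogenes higher in untreated axr2 exceeded every wild-type and msg2 array. The GAPDH 3' minus 5' control differences ran from −0.26 to 0.49 over the arrays and those of actin from 1.47 to 2.43. Both ends of the actin range lay in untreated axr2, at 1.47 on replicate 1 and 2.43 on replicate 2. GAPDH was at −0.12 and 0.36 on the same arrays, so the replicates of this group were unlike in these controls.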
